A study of Gossypium hirsutum with 6 samples.

How the data were processed

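Total RNA was extracted with guanidine thiocyanate, messenger RNA was enriched on oligo(dT) beads and fragmented, cDNA was made with random hexamers and amplified by PCR, and reads of about 50 bases came from an Illumina HiSeq instrument, per the labels' protocols. The deposited tables hold whole unique read counts for each UniGene sequence with at least 1 read, made by the authors, per the file headers. The total in each header equals the sum of its counts. The aligner, its settings and the UniGene release are not given in the sources used here. RPKM values were computed by the authors as reads per kilobase of UniGene sequence and scaled to the total of unique reads, and recomputation from the deposited counts gave them with a relative error of at most 7.92e-09. The tables also give sequence length (median 889 bases), the percent of each sequence covered by reads (a deposited coverage value), Gene Ontology terms and the best protein match of each sequence. Unlisted genes were taken as 0 reads. Reads that fit several near-identical UniGene sequences cannot be assigned here, so members of multigene families and homoeologous copies from the A and D subgenomes (storage proteins, histones, WRKY factors and the like) are uncertain individually. Strand was not stated. None of the UniGene identifiers matched the reference gene table (0 matches), so no coordinates are given. Names are those of the best match, which 17890 of 20166 genes had and 6651 had in an informative form. Only 1069 best matches were to Gossypium sequences, so most names come from other species and are not proof of function. Of the best matches 80 were a puroindoline, a name that no list uses.

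The 6 libraries were grouped by embryo type and stage as labelled, with 1 library per group. The depth was 4.9e+06 (somatic globular) to 5.9e+06 (zygotic cotyledonal) unique reads, and 3 reads, the most that a count of 0 allows at 95% confidence, equal 0.506 to 0.615 CPM (counts scaled to library size). Counts were scaled by TMM with factors from 0.850 (zygotic cotyledonal) to 1.09 (zygotic globular). Genes with at least 1 CPM in at least 2 libraries were tested (18970), and 1196 were not, of which 77 had at least 5 CPM in 1 library.

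Somatic and zygotic embryos were compared over the stages with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, stage and embryo type as terms, 2 residual degrees of freedom, prior degrees of freedom 3.86, common dispersion 0.241, a biological coefficient of variation of 49.1%), with Benjamini-Hochberg adjustment at 0.05. The residual holds the variation of the difference between stages and the library noise, since no group has replicates. Stage changes over both types were tested in the same fit. The p-values measure only the spread between these libraries. Log2 changes over the stages are given with standard errors. These were computed from the test, as the size of the change divided by the square root of its F statistic. A fold against a group without reads is a lower bound against 3 reads over the group, or per library within a stage. With 1 to 3 reads the ratio has an exact conditional interval.

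Pairs of single libraries were compared without a test. A gene was counted when its log2 ratio of scaled CPM (prior count 0.5) was at least 1 in size, the higher library had at least 5 CPM and the exact conditional 95% interval of the ratio, for counting error only, excluded a ratio of 1. Named ratios needed at least 20 CPM. PCR copies are not independent molecules, so true intervals are wider.

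Gene lists were fixed as word patterns on the best match: storage proteins, oil body, LEA and dehydrin, embryo regulators, heat shock, antioxidant, class III peroxidase, pathogenesis-related, disease resistance receptors, abscisic acid, jasmonate, ethylene, auxin, cytokinin, gibberellin, brassinosteroid, cell division, histones, chromatin modifiers, ribosomal proteins, photosynthesis, fatty acid and oil synthesis, lipid transfer, wall loosening, wall synthesis, phenylpropanoid and lignin, flavonoid, terpenoid, nitrogen metabolism, sugar use and fermentation, aquaporin, WRKY, MYB and NAC, expression references, and for tissues that samples could hold, fiber and seed coat, proanthocyanidin, endosperm and vascular or wound genes. The 38 lists took in 1617 genes. The cell division pattern also took in 42 RNA-directed DNA polymerases, and the LEA pattern took in a phloem protein below the count filter. The endosperm list, with 1 tested gene, was too small to test. The other 37 lists were tested over the stages with limma 3.58.1 on log2 CPM (prior count 2). Camera was run with a preset correlation of 0.01 and with an estimated one. Fry was also run, which tests whether the genes of a list move one way on balance. Medians of lists over the stages come from this fit, and are no bounds for genes at 0; with such genes at their bound the edgeR medians of the lists were as fitted. Within single comparisons a list's median was set among 10000 random lists of the same size matched on mean expression in 20 bins.

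Named genes were chosen by a rule: the 8 largest changes each way between embryo types among genes past the threshold with one sign at all stages, in each list the 2 most abundant and the 2 most changed genes, all embryo regulators, and the 5 largest ratios each way within a stage and from globular to cotyledonal. The groups, tests, lists, this rule and the alternatives were set before the data were examined. The alternatives were DESeq2 size factors and total read scaling, no count filter and one of 5 CPM, DESeq2 1.42.0, limma on log2(RPKM + 0.5) and log2(RPKM + 1), models without stage or type, each library or stage left out, other thresholds of the rule, and other prior counts. The following were added after seeing the data: the cell division list without polymerases, Gene Ontology terms, and single-library counts within stages and within types with all libraries thinned to the depth of the shallowest, the somatic globular library. Tables and ratios were computed in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

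The code was tested on counts simulated for this design with 200 changed genes. For the comparison of embryo types, edgeR recovered 35.8% of 67 genes changed 4-fold, 98.5% of 67 changed 16-fold and 100% of 66 changed 64-fold, with 8 false calls among 18970 genes tested. DESeq2 recovered 62.7%, 98.5% and 100% with 34 false calls, and limma 41.8%, 98.5% and 100% with 10. Camera called the shifted list and 0 of 20 random lists. For these tests the genes were simulated independently of each other with the common dispersion, and the false calls hold for that setting only. Lists whose genes vary together, such as histones with an estimated correlation of 0.641, were not simulated. For the globular stage, the rule of size took 47.8% of genes changed 2-fold and 100% of those changed 4-fold, with 41 false among 20166 genes, and 96.3% of its intervals held the true ratio.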

Results

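Messenger RNA was sequenced from somatic and zygotic embryos of upland cotton (Gossypium hirsutum, cultivar YZ1) at 3 parallel stages: globular, torpedo and cotyledonal. Zygotic embryos came from seeds of field-grown plants, and somatic embryos, which form from body cells without fertilization, came from embryogenic callus grown from hypocotyls. Each of the 6 combinations of embryo type and stage was measured in 1 library, so no group has replicates. The zygotic libraries held 5.4e+06 (globular), 5.2e+06 (torpedo) and 5.9e+06 (cotyledonal) unique reads, and the somatic libraries 4.9e+06, 5.0e+06 and 5.1e+06. Reads were listed for 18995 to 19539 UniGene sequences per library and for 20166 in any library, with a median of 75 to 94 reads per listed gene. A gene at 0 could have had up to 0.506 to 0.615 CPM (counts scaled to the size of the library), the value of 3 reads, depending on the library. Such floors, and all intervals given for single libraries, cover counting error only.

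The libraries separated by embryo type first. The first principal component of log2 CPM held 66.4% of the variance and the second 25.1%. Pearson correlations across genes, which are not independent replicates, were 0.967 to 0.971 between the somatic libraries and 0.519 to 0.628 between libraries of different type. Among zygotic libraries the torpedo and cotyledonal stages correlated at 0.926, while the globular library correlated with them at 0.762 and 0.688.

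**Figure D1:**
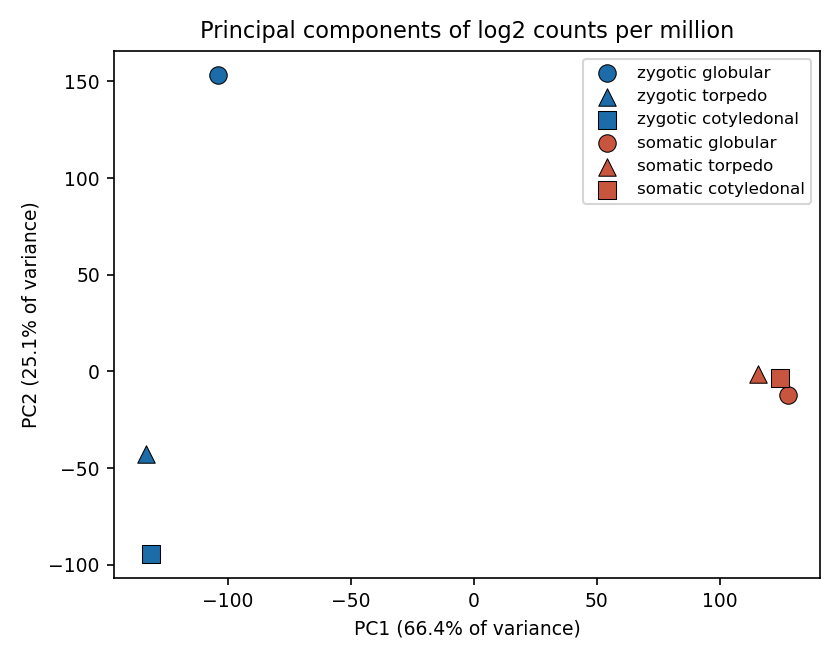
First principal component (horizontal, 66.4% of variance) against second (vertical, 25.1%) of log2 CPM, with 1 point per library, colour for embryo type and shape for stage. The 3 somatic libraries lie close together, and the zygotic globular library lies apart from the other zygotic libraries.

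The comparison of somatic with zygotic embryos over the 3 stages asks which genes differ between the embryo types whatever the stage. Of 18970 genes tested, 2930 differed, 1953 higher and 977 lower in somatic embryos (edgeR quasi-likelihood test with stage as a block, Benjamini-Hochberg adjusted p below 0.05). The sign was the same at all 3 stages for 2926 of them. The test favours this, because a difference that varies between stages seldom passes. Genes higher in somatic embryos included 6 of 9 LEA and dehydrin, 3 of 11 storage protein, 18 of 27 WRKY, 21 of 58 MYB and NAC, 21 of 53 gibberellin and 5 of 11 terpenoid genes, and genes lower there included 15 of 38 histones. Each of these lists was called by camera with a preset correlation and none with an estimated one (lowest adjusted p = 0.446 with an estimated correlation). Of the 2930 genes, 89 had no read in any zygotic library and 42 none in any somatic library. The spread in this test is the variation of the difference between stages, with 2 residual degrees of freedom; the stages are not replicates. Single libraries decided the number of calls: it was 0 without the zygotic torpedo library (3302 at an unadjusted p below 0.05), 205 without the somatic torpedo, 571 without the zygotic cotyledonal and 889 without the somatic cotyledonal library, but 7182 without the zygotic globular and 7171 without the somatic globular library. DESeq2 called 4736 genes, and edgeR without the stage term 4916.

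Seed maturation genes were high in every somatic library, whereas in zygotic embryos they were low at the globular stage. Storage protein genes summed to 186, 904 and 19438 CPM at the zygotic globular, torpedo and cotyledonal stages and to 34541, 34529 and 51066 in the somatic libraries. The storage protein gene Ghi.8038 had no read in any zygotic library and 8040, 7943 and 13120 CPM in the somatic globular, torpedo and cotyledonal libraries, at least 52600-fold higher against a floor of 3 reads over the zygotic group (edgeR, Benjamini-Hochberg adjusted p 0.0219). Late embryogenesis abundant (LEA) proteins accumulate as embryos acquire desiccation tolerance. LEA D-11 (Ghi.8041) averaged 3884 ± 624 CPM in somatic libraries (SD, 3 stages), a ratio of 31470 with a 95% counting interval from 8712 to 259900. A second LEA gene (Ghi.8162) was 15490-fold higher (4287 to 127900), and LEA D-7 (Ghi.8097) was higher by 10.46 ± 1.55 on the log2 scale (SE). Of 9 LEA and dehydrin genes tested, 6 were higher and 0 lower over all genes tested, and 8 were higher adjusted over the list alone. Their median log2 difference was 7.55 (limma camera, Benjamini-Hochberg adjusted p 9.54e-06, and adjusted p = 0.446 with an estimated correlation). For storage proteins, the reserves of the mature embryo, 3 of 11 genes were higher and 0 lower, with 5 higher adjusted over the list alone; the median was 6.02 (camera adjusted p 0.000982, and adjusted p = 0.617 with an estimated correlation). Vicilin C72 (Ghi.16457) was at 3.08, 274 and 10200 CPM along the zygotic stages and at 7938 to 12110 in somatic libraries, and its difference over the stages did not pass the test (5.16 ± 2.94, adjusted p 0.277). Of 8 oil body genes, 2 were higher and 0 lower, with 4 higher adjusted over the list alone and a median of 5.57 (camera adjusted p 0.00360, and adjusted p = 0.603 with an estimated correlation). Caleosin (Ghi.24905) was among them (6.002 ± 0.66), while the most abundant oleosin (Ghi.5525) was not (1.96 ± 2.37). Of 80 genes chosen by rule that passed the test here and in the next paragraphs, 77 lost the call without the zygotic torpedo library, 56 without the somatic torpedo, 32 without the zygotic cotyledonal and 27 without the somatic cotyledonal library.

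**Figure D2:**
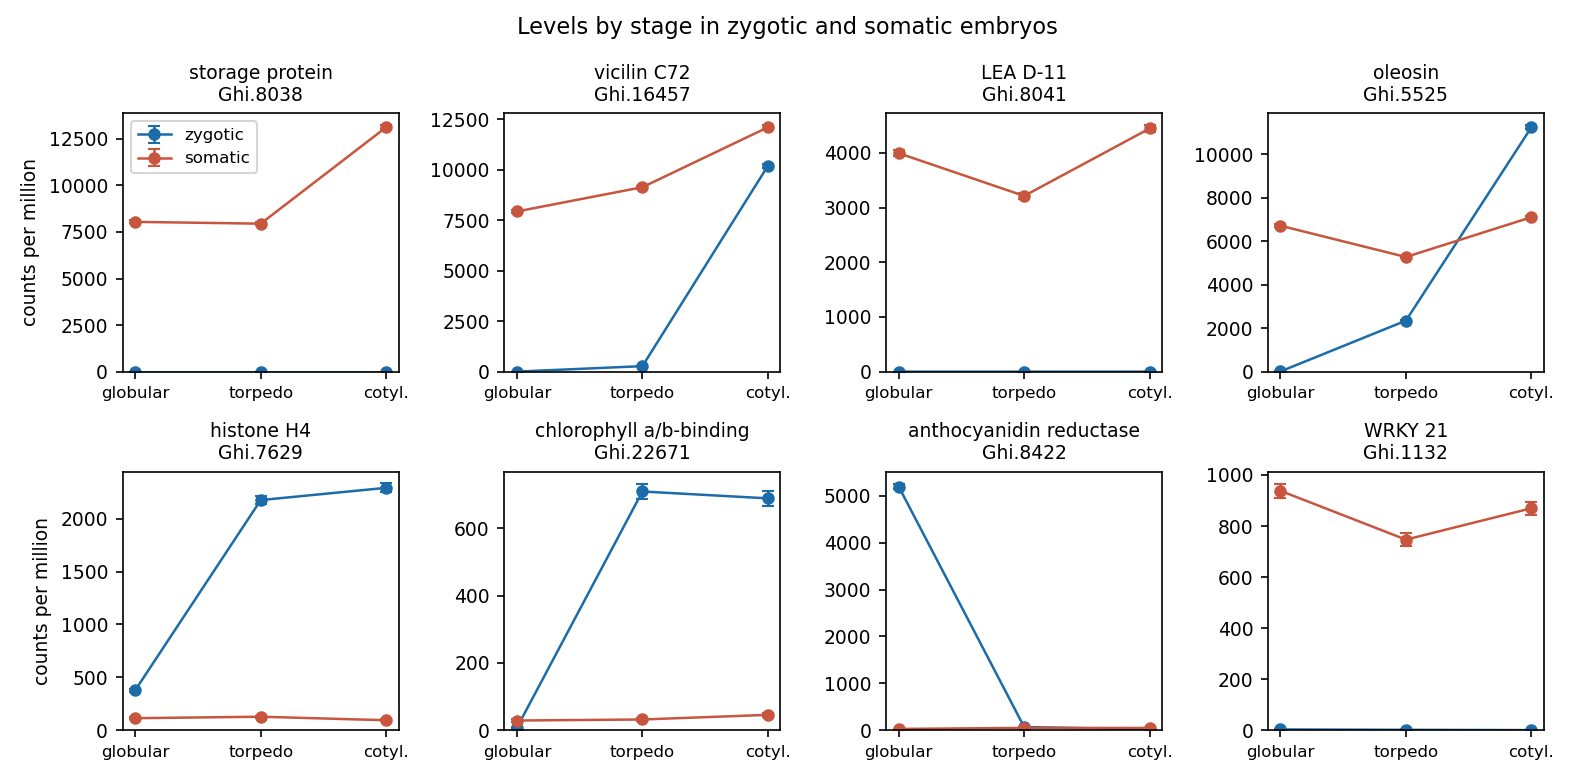
Scaled CPM (counts relative to library size, vertical, linear, from 0) of 8 genes at the 3 stages in zygotic (blue) and somatic (red) embryos, 1 library per point, with exact 95% Poisson intervals of the count. The storage protein Ghi.8038 reached 13120 CPM in somatic and 0 in zygotic libraries, while anthocyanidin reductase Ghi.8422 stood at 5196 in the zygotic globular library alone.

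Transcription factor and hormone genes also differed between the embryo types. Of 27 WRKY factors, many of them responsive to stress, 18 were higher and 0 lower, both over all genes and adjusted over the list alone, with a median of 4.22 (camera adjusted p 2.10e-08, and adjusted p = 0.446 with an estimated correlation). WRKY 16 (Ghi.3139) had no zygotic read and was at least 1118-fold higher, and WRKY 21 (Ghi.1132) had at most 2.74 CPM in zygotic libraries and 747 to 938 in somatic ones (9.48 ± 1.03). Of 58 MYB and NAC factors, 21 were higher and 0 lower (31 and 3 adjusted over the list alone), with a median of 1.46 (camera adjusted p 1.64e-05, and adjusted p = 0.446 with an estimated correlation). NAC2 (Ghi.3264) was higher by 5.71 ± 0.86, and Myb 5 (Ghi.15657) was at least 359-fold higher. Gibberellin genes numbered 21 higher and 2 lower of 53 (22 and 5 adjusted over the list alone, median 1.17, camera adjusted p 0.000588, and adjusted p = 0.446 with an estimated correlation). Gibberellin 3-beta-dioxygenases, the enzymes of the last activating step, were among the strongest: Ghi.24731 was at least 1974-fold higher and Ghi.760 higher by 13.02 ± 1.37. Gibberellin 20-oxidase 1 (Ghi.17176) stood at 10360 CPM in the zygotic globular library and at 16.1 to 316 in the others, with no call (0.76 ± 2.41). For ethylene, 12 of 54 genes were higher and 0 lower (13 and 0 adjusted over the list alone, median 1.07, camera adjusted p 0.000688, and adjusted p = 0.617 with an estimated correlation), including an ACC synthase (Ghi.16541) at least 261-fold higher. Abscisic acid genes gave 5 higher and 0 lower of 26 (6 and 0 adjusted over the list alone, median 0.82, camera adjusted p 0.0153, and adjusted p = 0.517 with an estimated correlation), and the list's adjusted p was 0.0515 without the globular stage. Jasmonate genes gave 2 higher and 0 lower of 23 (1 and 0 adjusted over the list alone, median 1.56, camera adjusted p 0.0253, and adjusted p = 0.679 with an estimated correlation), with an adjusted p of 0.0832 without the torpedo stage; a lipoxygenase (Ghi.16252) was higher by 5.95 ± 0.57. No camera call was made for auxin (14 higher and 5 lower of 86, 17 and 6 adjusted over the list alone, median 0.36), cytokinin (3 and 2 of 20, 3 and 3 adjusted over the list alone, median -0.18 with fry pointing up) or brassinosteroid genes (1 and 0 of 16, 2 and 1 adjusted over the list alone, median 0.17). Within these, the response regulator ARR8 (Ghi.11041) was higher by 5.06 ± 0.54 and a cytokinin oxidase (Ghi.261), which degrades cytokinin, fell by 4.72 ± 1.04.

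Stress, defence and metabolism lists held genes that passed the test in somatic embryos, although most members of each list in this paragraph did not pass. Of 11 terpenoid genes, which in cotton include the gossypol pathway, 5 were higher and 0 lower (6 and 1 adjusted over the list alone), with a median of 1.35 (camera adjusted p 0.00538, and adjusted p = 0.517 with an estimated correlation). The delta-cadinene synthases Ghi.16945 (8.26 ± 0.95) and Ghi.17288 (11.34 ± 0.97) led them. Heat shock genes gave 16 higher and 1 lower of 65 (18 and 2 adjusted over the list alone, median 0.46, camera adjusted p 0.0334, and adjusted p = 0.517 with an estimated correlation), and the list's adjusted p was 0.0514 without the cotyledonal stage. Disease resistance receptors gave 7 higher and 0 lower of 24 (8 and 1 adjusted over the list alone, median 1.16, camera adjusted p 0.00411, and adjusted p = 0.737 with an estimated correlation). Genes of sugar use and fermentation gave 14 higher and 3 lower of 59 (18 and 4 adjusted over the list alone, median 0.33, camera adjusted p 0.0355, and adjusted p = 0.517 with an estimated correlation), with an adjusted p of 0.0535 without the torpedo stage. A non-symbiotic hemoglobin (Ghi.8085) reached 5764 to 7240 CPM in somatic libraries against 0.171 to 82.1 in zygotic ones, without passing the test (8.02 ± 2.19, adjusted p 0.0618). Antioxidant genes had 13 higher and 5 lower of 61 (15 and 10 adjusted over the list alone) and no camera call; their median was -0.04, their mean 0.72, and camera pointed down while fry pointed up (fry adjusted p 0.0389). The glutathione S-transferases Ghi.20887 and Ghi.3697 were at least 999-fold and 931-fold higher. Pathogenesis-related genes had 16 higher and 9 lower of 55 (19 and 13 adjusted over the list alone), with a median of -0.07, a mean of 0.96 and camera and fry both up, but only fry below 0.05 (adjusted p 0.0259); the PR10-5-like gene Ghi.6523 was at least 1195-fold higher. Class III peroxidases (8 and 4 of 25, 11 and 6 adjusted over the list alone, median 0.47) had no camera call, nor had nitrogen metabolism genes (2 and 0 of 10, the same adjusted over the list alone, median 0.91). Nitrite reductase (Ghi.3170), which supplies ammonium from nitrite, was higher by 6.79 ± 0.98, and an ammonium transporter (Ghi.3172) by 5.67 ± 0.88. Without the globular stage the peroxidase and nitrogen lists were called, with camera adjusted p 0.0225 and 0.00580, and for both adjusted p = 0.5895 with an estimated correlation. Phenylpropanoid and lignin genes had no call (7 and 3 of 41, the same adjusted over the list alone), with a median of -0.08 in log2 CPM, a mean of 0.59, a median of 0.42 in the edgeR fit and an adjusted p of 0.0377 without the globular stage (adjusted p = 0.5895 with an estimated correlation).

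Genes lower in somatic embryos included 15 of 38 histones, and 4 of the 8 largest decreases among genes with an informative name were MADS box genes, a family for which no list was fixed or tested. These genes, Ghi.6927, GHMADS-1 (Ghi.16279), MADS-13 (Ghi.22482) and GHMADS-2 (Ghi.8447), had no somatic read and were at least 1376-fold, 1006-fold, 544-fold and 276-fold lower. These bounds rest on the zygotic globular library, as for Ghi.6927 at 726, 21.7 and 4.37 CPM along the stages. Without that library they were 67.4-fold, 47.7-fold, 83.6-fold and 38.9-fold. Sucrose transporter 1 (Ghi.8430) was at least 579-fold lower, a nodulin family gene (Ghi.12435) 160-fold and a putative transcription factor (Ghi.23402) 136-fold, each a lower bound. The H6-like gene (Ghi.25042) was 5553-fold higher in zygotic embryos (95% counting interval 996 to 219400). Without the zygotic globular library the bounds were 52.1-fold, 14.8-fold and 13.8-fold and the ratio was 1004 (179.5 to 39700). That library is also the one in which the proanthocyanidin genes, typical of the seed coat, summed to 10180 CPM, against 51.8 to 155 in the others. No histone gene was higher, 23 were lower adjusted over the list alone, and the list had a median of -2.73 (camera adjusted p 2.32e-09, and adjusted p = 0.617 with an estimated correlation). A histone H4 (Ghi.18432) fell by 5.90 ± 0.89 and a histone H3 (Ghi.9099) had -4.68 ± 1.08. The cell division list held 19 higher and 12 lower of 99 (29 and 19 adjusted over the list alone) with no camera call and a median of -0.02, a mean of 0.07 and camera pointing down; its 19 higher genes were all RNA-directed DNA polymerases, enzymes of retroelements that its pattern had taken in. Cyclin B (Ghi.22054) fell by 3.67 ± 0.66, and proliferating cell nuclear antigen (Ghi.3), the sliding clamp of DNA replication, was at 47.7 to 561 CPM in zygotic and 16.1 to 33.5 in somatic libraries without passing the test (-3.12 ± 1.06). Genes used as expression references gave 7 lower and 0 higher of 88 (1 lower adjusted over the list alone, median -1.05, camera adjusted p 1.64e-05, and adjusted p = 0.517 with an estimated correlation), and their direction was the same with total count scaling. Ribosomal proteins had 6 higher and 4 lower of 158 (2 higher and 0 lower adjusted over the list alone, median -0.61, camera adjusted p 0.000224, and adjusted p = 0.750 with an estimated correlation), with an adjusted p of 0.0776 without the cotyledonal stage.

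Photosynthesis genes had 1 lower and 0 higher of 40 (0 adjusted over the list alone, median -1.12, camera adjusted p 0.00360, and adjusted p = 0.650 with an estimated correlation). Chromatin modifiers had 1 lower and 0 higher of 33 (0 adjusted over the list alone, median -0.52, camera adjusted p 0.0253, and adjusted p = 0.617 with an estimated correlation), and an adjusted p of 0.0759 without the torpedo stage. Cell wall synthesis genes had 6 higher and 7 lower of 52 (7 and 10 adjusted over the list alone, median -1.06, camera adjusted p 0.0489, and adjusted p = 0.750 with an estimated correlation), with an adjusted p of 0.814 without the globular stage and fry pointing up. Flavonoid genes had 1 higher and 4 lower of 29 (the same adjusted over the list alone, median -1.23 in log2 CPM and -0.63 in the edgeR fit, camera adjusted p 0.0334, and adjusted p = 0.750 with an estimated correlation); without the globular stage their median was 0.44 and their adjusted p 0.739. Wall-loosening genes had 11 higher and 20 lower of 65 (13 and 22 adjusted over the list alone, median -0.41), fatty acid and oil synthesis genes 5 and 3 of 51 (the same adjusted over the list alone, median -0.48), and lipid transfer proteins 1 and 3 of 14 (1 and 4 adjusted over the list alone, median -1.27), without a camera call; the lipid transfer list had an adjusted p of 0.0164 without the cotyledonal stage (adjusted p = 0.800 with an estimated correlation). Aquaporins, the water channels, went both ways with 7 higher and 9 lower of 38 (9 and 9 adjusted over the list alone), a median of 0.16 and camera pointing down without a call. PIP1-2 (Ghi.4570) fell by 3.67 ± 0.76 and TIP2;2 (Ghi.6498) was higher by 5.43 ± 0.92.

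Of 6 genes that the embryo regulator list took in by name, 1 passed the test. BABY BOOM (Ghi.1250), a factor that can induce somatic embryos when overexpressed, was at 14.0, 95.3 and 55.6 CPM in zygotic and 53.1, 41.0 and 42.5 in somatic embryos (0.05 ± 0.68). The gene that was higher over all genes tested (1 higher and 1 lower adjusted over the list alone, median 0.11, no camera call) was a somatic embryogenesis receptor-like kinase (Ghi.17885), at 1.88 to 4.34 against 13.4 to 19.5 CPM (2.55 ± 0.51, edgeR with Benjamini-Hochberg adjusted p 0.0278). The other receptor kinases Ghi.12535 (-1.16 ± 0.34), Ghi.15373 (-0.99 ± 0.39) and Ghi.134 (0.13 ± 0.59) did not pass, nor did the LEC14B homolog Ghi.20985 (1.44 ± 0.49), which is a different protein from LEC1.

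Markers of tissues next to the embryos were measured in the same libraries. Genes named for the cotton fiber, a hair of the maternal seed coat, had 3 higher and 4 lower of 32 (4 and 4 adjusted over the list alone, median -0.64, camera adjusted p 0.0349, and adjusted p = 0.517 with an estimated correlation), with an adjusted p of 0.0656 without the globular stage. Fiber protein Fb31 (Ghi.16430) was at 728, 329 and 157 CPM in zygotic and 1.34 to 2.37 in somatic libraries, and E6 (Ghi.17553) at 248, 147 and 12.7 against 0.202 to 1.15. Proanthocyanidin genes, typical of the seed coat, gave 0 calls over all 7 genes and adjusted over the list alone (median -0.82 in log2 CPM, 0.09 in the edgeR fit, no camera call), but the zygotic globular library held 10180 CPM of them in sum, against 51.8 to 155 in the other 5. Without the cotyledonal stage that list had a camera adjusted p of 0.0252 (adjusted p = 0.844 with an estimated correlation). The endosperm list took in only 1 gene, by the word in its name, fertilization-independent endosperm (Ghi.7464), which showed 0.12 ± 0.37. A single gene matched by name does not measure endosperm in the samples. Of 6 genes named for vascular tissue or wounding 1 was higher, also adjusted over the list alone (median 0.06, mean -0.10, no camera call), the phloem protein ATPP2-A13 (Ghi.24696, 4.47 ± 0.39).

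Camera with a preset correlation called 21 of the 37 lists tested, 13 up and 8 down in somatic embryos. With an estimated correlation none was called, the lowest adjusted p being 0.446. Fry called 12, among them the antioxidant and pathogenesis-related lists, which camera had not called. Of the 8 lists that camera called lower, fry called only the fiber and seed coat list (fry adjusted p 0.0424). Histones, for example, had a fry adjusted p of 0.181.

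Within each stage, the somatic and zygotic libraries were compared by a fixed rule of size, to see at which stage the types differ. At the globular stage 4397 genes were higher and 3822 lower in the somatic library, at the torpedo stage 4135 and 3357, and at the cotyledonal stage 4640 and 3975. Storage protein genes had median log2 ratios of 11.98, 6.57 and 0.56 at the 3 stages, while LEA and dehydrin genes stayed at 5.84, 5.83 and 4.81 and WRKY genes at 3.41, 4.47 and 4.72. Histones went from -1.04 to -3.10 and -4.35, and at the cotyledonal stage 31 of 38 were lower by the rule. Photosynthesis genes were at 1.08, -2.22 and -1.96 and ribosomal proteins at 0.55, -0.93 and -1.34, so that the globular stage had the opposite sign. Flavonoid genes were at -4.07, 0.42 and 0.28 and proanthocyanidin genes at -7.06, 0.85 and 3.61. At the globular stage the subtilisin-like gene Ghi.22279 was at least 1181-fold lower in the somatic library. At the torpedo stage the alpha expansin Ghi.2039 was 766-fold higher in the zygotic library (95% counting interval 137 to 30280), and at the cotyledonal stage the histone H3 gene Ghi.4281 was 140-fold higher there (112 to 179). Of 15531 genes with enough reads, all 3 stages shared 2175 higher in somatic libraries, where independence would give 303. They shared 1064 lower, where it would give 124. An excess over independence was likely in advance, because the somatic libraries correlated at 0.967 to 0.971 with each other. Over all genes, 864 went opposite ways at any 2 stages, a number for which no value under independence was computed. The somatic over zygotic ratios correlated across genes at 0.658 between globular and torpedo stages, 0.549 between globular and cotyledonal and 0.854 between torpedo and cotyledonal (Spearman 0.532, 0.449 and 0.803).

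**Figure D3:**
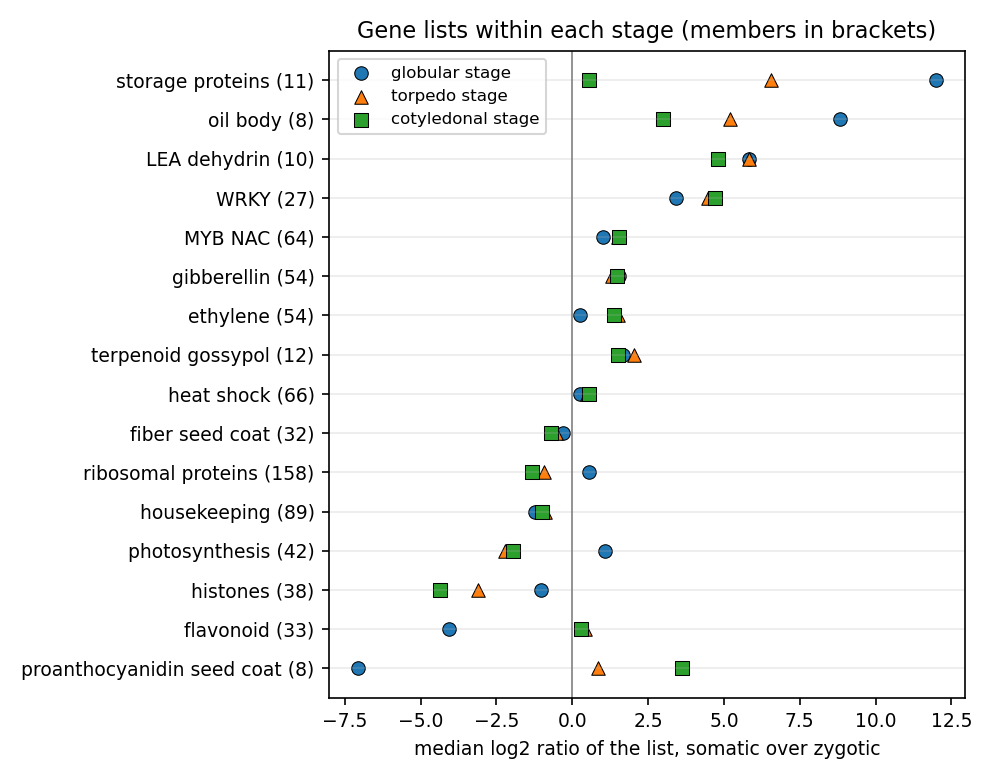
Median log2 ratio of somatic over zygotic CPM (horizontal) for 16 gene lists (vertical, members in brackets), with 1 point per stage and 2 libraries behind each point. Storage proteins went from 11.98 at the globular to 0.56 at the cotyledonal stage, and proanthocyanidin genes from -7.06 to 3.61.

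These counts compare 2 libraries each, not the conditions, and have no replicate check. Scaling by total reads in place of TMM shifted all log2 ratios by -0.105 at the globular stage, where it turned the balance to 4066 higher and 4243 lower genes, and by 0.263 at the cotyledonal stage, where it gave 5509 higher and 3042 lower (64.4% against 53.9% higher). The deposited RPKM turned the balance at the globular stage to 4186 higher and 4271 lower, and a minimum of 20 CPM turned it at the cotyledonal stage to 2900 higher and 3125 lower.

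Along the zygotic course from globular to cotyledonal, 3932 genes were higher and 3958 lower by the same rule. Storage proteins had a median log2 ratio of 8.64, with 8 of 11 higher, and oil body genes 6.90, with 6 of 8 higher. The legumin gene Ghi.16459 was at least 777-fold higher and the vicilin GC72-A gene Ghi.8748 was 5628-fold higher (95% counting interval 1925 to 27290). Photosynthesis genes (3.32, 27 of 42 higher and 3 lower), histones (2.43, 32 of 38 higher and 0 lower) and ribosomal proteins (1.77, 124 of 158 higher and 11 lower) had positive medians. Flavonoid genes (-2.22, 4 higher and 19 lower of 33), proanthocyanidin genes (-8.73, 8 of 8 lower) and nitrogen metabolism genes (-4.34, 1 higher and 7 lower of 10) had negative ones. Anthocyanidin reductase (Ghi.8422), which makes epicatechin units, stood at 5196, 67.8 and 13.7 CPM along the stages, and flavonoid 3'5'-hydroxylase (Ghi.16280) at 9787, 63.8 and 34.8. The leucoanthocyanidin reductase Ghi.17301 was at least 342-fold and a vacuolar invertase (Ghi.4486) at least 387-fold lower at the cotyledonal stage. From globular to torpedo 3232 genes were higher and 3508 lower, and from torpedo to cotyledonal 1638 and 1255. Each count compares 2 libraries. Total read scaling shifted the 3 zygotic comparisons by -0.361 (cotyledonal over globular), -0.102 (torpedo over globular) and -0.259 (cotyledonal over torpedo), with 2778 higher and 5258 lower for the first (34.6% against 49.8% higher) and 1024 and 2115 for the last (32.6% against 56.6%). The deposited RPKM gave 1046 and 2137 for the last. A minimum of 20 CPM turned the balance to 2954 higher and 2406 lower from globular to cotyledonal and to 2362 and 2134 from globular to torpedo.

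The somatic libraries differed far less between stages, with 411 genes higher and 267 lower from globular to cotyledonal, 360 and 256 from globular to torpedo and 384 and 214 from torpedo to cotyledonal. The storage protein and oil body lists had medians of 0.35 and 0.30 from globular to cotyledonal. Photosynthesis genes had a median of 0.66, with 12 of 42 higher and 0 lower, aquaporins 0.57, with 10 of 38 higher, and flavonoid genes 0.56, with 9 of 33 higher and 1 lower. Terpenoid genes went the other way, with the list median largest in size (-0.86) but only 2 lower and 0 higher of 12. The tonoplast aquaporin TIP2;2 (Ghi.6498) was 17.1-fold higher (95% counting interval 12.2 to 24.8), the Rubisco small subunit (Ghi.1513) 7.53-fold (5.74 to 10.1) and a plastocyanin (Ghi.10669) 6.69-fold (4.01 to 11.9). The fasciclin-like arabinogalactan protein gene Ghi.17358 was 8.67-fold higher (5.45 to 14.5). Among lower genes, a histidine phosphotransfer gene (Ghi.1296) was 4.18-fold higher at the globular stage (3.20 to 5.52), the gibberellin 3-beta-dioxygenase Ghi.9268 3.44-fold (3.02 to 3.93) and a GH3 family gene (Ghi.23624) 3.30-fold (2.21 to 5.04).

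The stage changes of the embryo types were compared across genes, to see whether both courses move alike. From globular to cotyledonal the somatic and zygotic log2 ratios correlated at -0.085 (Pearson, 95% bootstrap interval over genes -0.108 to -0.0630) and -0.140 (Spearman) over 18970 genes. Genes are not independent replicates, so this interval does not cover the spread between libraries. Of 14309 genes that reached the minimum in both courses, 112 were higher in both, where independent lists would share 80.5, and 46 lower in both, where they would share 33.7. Another 140 genes were lower in zygotic and higher in somatic embryos, where independent lists would share 69.9. The reverse held for 60 genes, where they would share 38.8, so opposite changes also exceeded independence. In the joint edgeR test over both embryo types 0 genes passed for cotyledonal against globular, torpedo against globular and cotyledonal against torpedo, with 455, 262 and 131 genes at an unadjusted p below 0.05. DESeq2 gave 63, 11 and 0 and limma on log2 RPKM 0, 0 and 0. Without the somatic globular library edgeR called many genes against globular, but that stage then rested on the zygotic globular library alone. Such calls describe that library, not a change over both embryo types. For cotyledonal against torpedo edgeR gave 1 gene without the somatic and 8 without the zygotic globular library.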

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

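The patterns in this part, and the tests of explanations for them, the comparison at one depth and the comparison with the zygotic course included, were chosen after the results were seen; for those 2 comparisons what each explanation predicts was set down before the test was run. Between the globular and the cotyledonal stage, 5 gene lists had medians, and 7 named genes log2 ratios, of opposite sign in zygotic and somatic embryos, each group being 2 libraries; whether these changes differ was not tested. The lists are those below the central 95% of 10000 random lists in one type and above it in the other. Their median log2 ratios, zygotic then somatic, were -1.653 and 0.4426 for cell wall synthesis, -2.223 and 0.5642 for flavonoid genes, -8.733 and 0.627 for proanthocyanidin genes, 1.774 and -0.1856 for ribosomal proteins, and -0.2766 and 0.06383 for expression reference genes. By the rule of size few members changed in somatic embryos: 7 higher and 0 lower of 56 for cell wall synthesis, 9 and 1 of 33 for flavonoid, 2 and 0 of 8 for proanthocyanidin, 0 and 7 of 158 for ribosomal protein and 3 and 0 of 89 for expression reference genes. For single genes the log2 ratios were -1.947 and 1.714 for a polygalacturonase-inhibiting protein (Ghi.10609), -8.133 and 1.195 for flavonoid 3'5'-hydroxylase (Ghi.16280), -6.296 and 3.084 for a fasciclin-like arabinogalactan protein (Ghi.17358) and -9.623 and 1.593 for leucoanthocyanidin reductase 1 (Ghi.18163). They were 1.49 and -1.232 for cyclin B (Ghi.22054), 3.555 and -1.057 for proliferating cell nuclear antigen (Ghi.3) and 6.855 and -2.004 for a DNA binding protein (Ghi.4471).

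Seed maturation genes were high in all 3 somatic libraries, including the globular one. If somatic embryos were simply ahead on the zygotic course, genes that rise along it would also be higher in somatic globular than in zygotic torpedo embryos. Across 18942 genes outside the maturation lists the correlation was -0.1723 (95% bootstrap interval -0.1943 to -0.1509), so this prediction was not met. That interval is over genes and does not cover the spread between libraries. For the 28 maturation genes, which show the pattern, the correlation was only 0.03238, so the measure hardly detects the pattern itself. The zygotic torpedo library also correlated more with the cotyledonal (0.926) than with the globular library (0.762), and subtracting it lowers the measure. A general advance therefore stays open. Reads shared between near-identical copies stay open: the summed storage protein CPM at the torpedo stage were 38.18 times as high in somatic embryos, but this sum is the pattern itself and, with unique counting, leaves shared reads out, so it decides nothing. A candidate explanation that stays open is a maturation or stress programme that culture starts apart from embryo shape, which was not tested and is confounded with embryo type.

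Proanthocyanidin genes stood high in the zygotic globular library alone. Scaling is argued against by its size, since total reads in place of TMM shift log2 ratios of zygotic cotyledonal over globular by -0.361. The median of the list was -8.733 with TMM and -9.094 with total read scaling, an outcome that this shift fixed in advance. Maternal seed coat tissue around small embryos may account for it, and cannot be told apart here from expression in the embryo itself: the list of fiber and seed coat genes had a median of 0.4106 in the same comparison, with 8 genes higher, 10 lower and 14 neither. At their own levels the members went both ways. Fb31 (Ghi.16430) was at 728 CPM in the zygotic globular and 157 in the zygotic cotyledonal library. The other fiber gene whose levels are given above also fell along the zygotic stages, while Ghfe1 (Ghi.1644) was at 1298 and 3081. The median of such a mixed list therefore does not decide for or against seed coat tissue. A difference between embryo stages stays open and was not tested apart from tissue.

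Few genes differed between the somatic stages. A library deposited more than once is argued against, because the counts of each pair of somatic libraries differed by more than sampling noise, with a dispersion index of at least 8.278 where identical samples give about 1. Lower depth is argued against too, since with all libraries thinned to the depth of the shallowest the zygotic cotyledonal and globular libraries still differed in 7909 genes and the somatic ones in 688. Embryos of several stages mixed in each somatic sample may damp the changes, and the correlation of somatic with zygotic changes, -0.08523, does not decide it, because complete mixing would leave only differences unrelated to stage. The embryo type itself stays open, since culture and origin differ with it.

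The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2930 genes and the highest of the other splits 0, so 1 of 10 splits gave as many genes. The other splits leave most of the difference between embryo types in the residual, so few calls were likely in advance. Many of them also put both libraries of a stage on the same side. The splits therefore decide nothing.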

How the results depend on the processing

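Settings chosen after the results were seen were the cell division list without polymerases (57 genes, 12 lower and 0 higher, median log2 -1.07, camera adjusted p 7.15e-06, and adjusted p = 0.456 with an estimated correlation) and thinning to one depth, which gave 8225, 7542 and 8636 genes within the stages, 6778, 7909 and 2935 between zygotic and 623, 688 and 627 between somatic stages; Gene Ontology terms, also added, are given under other observations. No paired analysis was possible because each group holds 1 library, so replicate numbers pair nothing; in the test between embryo types the stage pairs the libraries, and the count without it is given below. All alternatives set beforehand were run. Leaving out a library leaves 1 residual degree of freedom, and the remaining library of that stage then carries no information on the difference. Depth limits genes near 3 reads, and without replicates the type by stage variation cannot be parted from library noise.

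The 2930 genes between embryo types became 4736 with DESeq2 (2915 shared) and 4916 without the stage term (2856 shared), and 0 to 7182 with 1 library left out; total scaling, size factors and the 2 filters gave 2869 to 2936, with 2775 to 2863 shared, and limma 3425 and 3463. For the stage tests, 0 in each case, DESeq2 gave 63 for cotyledonal and 11 for torpedo against globular, and leaving out a library gave 0 to 3916, 0 to 3348 and, for cotyledonal against torpedo, 0 to 8. A log2 ratio of 2 gave 3972, 3411 and 4116 genes within the stages, 2767 (torpedo over globular), 3476 (cotyledonal over globular) and 599 (cotyledonal over torpedo) in zygotic and 47, 79 and 13 in somatic embryos, fewer by construction. A minimum of 20 CPM gave 1652 for zygotic cotyledonal over torpedo and 214, 261 and 233 in somatic embryos. The correlation of globular with torpedo ratios became 0.6863 at 5 and 0.7353 at 20 CPM and 0.6411 with a prior count of 5; globular with cotyledonal became 0.5905 and 0.6607; torpedo with cotyledonal 0.8827 and 0.9119, 0.8705 with the prior count and 0.8651 from RPKM.

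Of 37 lists, camera called 21, with an estimated correlation 0, and 18 to 21 under the other settings. Fry called 12, not all of them among the 21. Medians that changed sign, none past the threshold except where said, were antioxidant 0.01256 (total scaling) and 0.001459 (without globular), aquaporin -0.2711, brassinosteroid -0.1141 and vascular or wound genes -0.3247 (without torpedo), cell division 0.02982 (total scaling), 0.09303 (5 CPM) and 0.1535 (without torpedo), class III peroxidase -0.7614 (without cotyledonal), cytokinin 0.1954 (5 CPM), phenylpropanoid 0.4169 (5 CPM), and without globular embryo regulators -0.454, flavonoid 0.4397, proanthocyanidin 2.058 and phenylpropanoid 0.8121, the last past the threshold.

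Of 149 named genes the 80 past the threshold never changed sign; DESeq2 lost 3 of these calls and gained 22, limma lost 7 or 8. Of the other 69, 18 changed sign in 56 of 959 estimates, none past the threshold. Without the stage term these were Ghi.10275 -0.02045, Ghi.1250 -0.2714, Ghi.16409 -0.2918, Ghi.17176 -3.995, Ghi.18163 -4.257, Ghi.2173 -3.963 and Ghi.9244 -0.1885. With limma on log2(RPKM + 0.5) and log2(RPKM + 1), Ghi.17176 gave -0.3351 and -0.3565, Ghi.18163 -0.4846 and -0.565, and Ghi.2173 -0.4777 and -0.5402. With 1 library left out the lowest and highest log2 changes were Ghi.10149 -0.9478 and 0.3217, Ghi.1250 -0.8083 and 0.7598, Ghi.12623 -0.9626 and 0.2407, Ghi.134 -0.1788 and 0.5964, Ghi.1342 -0.1745 and 0.005538, Ghi.13441 -0.9931 and 0.2795, Ghi.16280 -4.329 and 0.3584, Ghi.16409 -0.6705 and 1.268, Ghi.17176 -2.394 and 2.513, Ghi.17914 -1.263 and 0.1597, Ghi.18163 -2.809 and 2.73, Ghi.2173 -2.541 and 2.375, Ghi.4426 -2.864 and 0.955, Ghi.7464 -0.1425 and 0.4053, Ghi.8422 -4.075 and 0.625, Ghi.8777 -0.3916 and 0.1065, and Ghi.9244 -0.4472 and 1.058. Except where the construction shows it, the cause was not tested.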

Other observations

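Gene Ontology process terms of the deposited annotation, chosen for testing after the results were seen, gave further groups. Of 220 terms with at least 15 tested genes, camera with Benjamini-Hochberg adjustment called 11 higher and 21 lower in somatic embryos over the 3 stages, and none with an estimated correlation (lowest adjusted p = 0.923 with an estimated correlation). Of 81 genes annotated to the response to carbohydrate stimulus, 37 were higher and 0 lower in edgeR, with a median log2 difference of 2.18 (camera adjusted p 2.38e-10, and adjusted p = 0.923 with an estimated correlation). Of 21 genes of programmed cell death 9 were higher and 1 lower (median 2.39, camera adjusted p 0.0156, and adjusted p = 0.923 with an estimated correlation). Isoprenoid metabolic process had 6 higher and 0 lower of 15 (median 1.34, camera adjusted p 0.0168, and adjusted p = 0.923 with an estimated correlation), and defense response to fungus 9 higher and 1 lower of 29 (median 1.02, camera adjusted p 0.0398, and adjusted p = 0.923 with an estimated correlation). Among terms that were lower, microtubule-based process had 18 lower and 0 higher of 95 genes (median -1.36, camera adjusted p 3.75e-11, and adjusted p = 0.923 with an estimated correlation) and DNA metabolic process 11 lower and 0 higher of 106 (median -0.58, camera adjusted p 0.000848, and adjusted p = 0.931 with an estimated correlation).

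The 42 RNA-directed DNA polymerases taken in by the cell division pattern, enzymes encoded by retroelements, had 19 genes higher and 0 lower in somatic embryos, with a median log2 difference of 1.79. They were looked at as a group after their values were seen, and reads of repeated elements are among those that unique counting assigns least surely.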
